A study of Mus musculus with 281 samples.

How the data were processed

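Single cells from mouse bone marrow were sorted by the gates in the labels and 281 of them were analysed, 1 per deposited sample. Per the labels' protocols, RNA was taken up in a picopure extraction buffer, cDNA was made by SMART-seq2 with a modified lysis buffer, libraries were made with a reduced Nextera XT reaction, and paired-end reads were run on an Illumina HiSeq 4000. The authors deposited 1 table of TPM values, transcript abundances relative to the cell's total, for all cells, with gene symbols as names. Per the submitters' processing notes, RSEM 1.2.19 and the genome build GRCm38 were used. The aligner, the annotation and the filters are not given in the sources used here. TPM divides by transcript length and by each cell's total, so the read depth of a cell is unknown and only the number of detected genes remains as a measure of it. The method has no molecular identifiers, and the levels are relative within a cell, so a very abundant transcript lowers all others.

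The table held 43280 symbols, of which 25450 were at 0 in every cell, and column totals ran from 998703 to 1000000. Every one of the 281 columns matched a sample title. No 2 cells had identical values, and Actb, B2m, Eef1a1 and Gapdh were above 0 in every cell. Gene positions are those of GRCm38 in the GENCODE M21 annotation, counted from 1; 39469 symbols (91.2%) were found there, and the annotation the authors used may differ. Reads of near-identical family members, such as Ly6c1 and Ly6c2 or the Ms4a6 genes, are shared out by estimate in RSEM, so the values of such genes are less certain than others. Reads of overlapping or antisense genes cannot be separated either, as the kit does not mark strand.

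Cells were grouped by the cell type label. Comparisons were Ly6C-GMP with CMP, Ly6C+GMP with Ly6C-GMP, proneu with Ly6C+GMP, preNeu with proneu, tpMo with Ly6C+GMP and tpMo with preNeu. The comparisons, gene lists, naming rule, cluster settings and the main alternatives were fixed before the data were examined. As each sample is 1 cell and no animal or culture is named, each group is 1 sample, and no test, p-value or standard error was computed from cells. The effect was the difference between groups of the mean over cells of log2(TPM + 1), which understates the difference of low genes; mean TPM with its SD over cells is given beside it. A gene was detected in a cell at 1 TPM or more. Shares of cells have exact Clopper-Pearson 95% intervals, and a count of 0 is given with the upper limit of that interval where a limit is named.

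The 17 gene lists covered primary granule, secondary and late granule, neutrophil regulator, monocyte, dendritic cell, erythroid and megakaryocyte, basophil and mast cell, eosinophil, stem and multipotent progenitor, lymphoid, DNA replication, mitosis, immediate early and heat shock, interferon response, gate surface protein, ribosome biogenesis and mitochondrially encoded genes. In all, 1 list member had no symbol in the table. Members with a mean of at least 1 TPM in either group were used, and a member counted as higher or lower from a difference of 1 log2 unit. Each list's median difference was placed among 10000 random lists of the same size, drawn from 25 bins of mean expression, as a description of these cells. Named genes were, per comparison, the 10 with the largest difference each way and up to 3 members of each list with the largest absolute difference. The first kind needed a mean of at least 50 TPM, detection in at least 50% of cells of the higher group and a ratio of means in the same direction, and could not be predicted or ribosomal protein genes. List members needed at least 5 TPM in the higher group. From the 58 to 62 genes so named per comparison, those described were picked for their function after their values were seen. Values within title runs were computed where a run held both labels.

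Ly6C-GMP, Ly6C+GMP and proneu cells were clustered on log2(TPM + 1) of genes detected in at least 5 cells, with the 2000 most variable genes after a running mean trend over 201 genes, 20 principal components, 15 neighbours, Leiden resolution 1 and seed 0. Cluster-defining genes are not reported as results. Doublets were not called, and no cell was left out. Alternatives were pseudocounts of 10 and 0.1 TPM, no filter on low values, the log2 ratio of mean TPM, median-ratio scaling over 547 genes detected in at least 90% of cells, renormalising without the mitochondrially encoded and the 20 most abundant genes, single title runs, Ly6C+GMP cells of 1 run, other cluster settings and other detection limits. After the data were seen, each named gene's mean was also taken without its highest cell: of 209 means of a gene in a label, 40 fell by more than 1.5 times, and those printed are given both ways (S100a8 in Ly6C-GMP cells without 3 cells, S100a10 in preNeu cells as detected in 1 cell). Of the 114 log2 differences over all cells, none shifted by more than 0.35. Means and differences within title runs were not checked in this way. A planned exclusion of cells with fewer than 1000 detected genes removed 0 cells, so it tested nothing.

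The code was tested on simulated data made from the cells of each comparison's reference group, in which 200 genes were raised or lowered 4-fold in a random part of those cells. The shifted genes and the lists made for this test had a mean of at least 50 TPM and detection in at least 50% of those cells. Lower genes, which the real lists also hold, were not tested. The sign was right for 93% of them with CMP cells over 11850 genes (for Ly6C-GMP with CMP), for 94.5% over 11840 genes (Ly6C+GMP with Ly6C-GMP), for 98% over 12167 (proneu with Ly6C+GMP), for 87% over 10504 (preNeu with proneu), for 98.5% over 12177 (tpMo with Ly6C+GMP) and for 87% over 8646 (tpMo with preNeu). Lists made of raised genes reached percentile 100 in each, and lists of lowered genes percentile 0 to 0.02. Lists of genes left unchanged lay at percentiles from 2.95 to 93.2. With 30 of 95 run A cells raised 8-fold in 200 genes, 4 clusters were found and 96.8% of cells belonged to the majority kind, shifted or not, of their cluster. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9 were used.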

Results

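To describe the heterogeneity of granulocyte-monocyte progenitors (GMPs), 281 single cells from the bone marrow of C57BL/6 mice, an inbred laboratory strain, were profiled by SMART-seq2, a full-length single-cell RNA-sequencing method. The labels gave the groups CMP (47 cells), Ly6C-GMP (45), Ly6C+GMP (95 and 10 in separate stretches of the sample titles), proneu (22), preNeu (31) and tpMo (31). The CMP gate and both GMP gates took lineage-negative, c-Kit-positive, Sca-1-negative, CD34-positive cells. CD16/32, a pair of Fc receptors, was low in the CMP gate and high in the GMP gates, which differed from each other in Ly6C, a surface protein of monocytes and their progenitors. The preNeu gate took Gr1-positive, CD11b-positive, c-Kit-positive and CXCR4-positive cells without CD115 or SiglecF, and the tpMo gate took CD115-positive, Ly6C-positive and CXCR4-positive cells without c-Kit. The gate given for 21 of the proneu cells was that of Ly6C+GMP, and the other proneu cell had no gate label. Whether the proneu label was assigned from the same transcriptomes is not stated; if it was, differences between proneu and Ly6C+GMP cells hold partly by construction.

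Sample titles carried the prefix RHP, called title run H here, or RMB. The RMB numbers ran on without a gap and were split here into title runs A, B and C where the set of labels changes. The labels state no meaning for the numbers, so these borders need not be borders of batches. Run A held 95 Ly6C+GMP cells. Run B held 31 CMP, 30 Ly6C-GMP and 1 proneu cell, and run H held 16 CMP and 15 Ly6C-GMP cells. Run C held 10 Ly6C+GMP, 21 proneu, 31 preNeu and 31 tpMo cells. Each cell was a sample of its own and no animal was named, so every group counts as 1 sample: no test was made, the differences have no replicate check, and each SD is the spread from cell to cell. Differences are of mean log2(TPM + 1) unless a ratio of mean TPM, the relative transcript abundance within a cell, is named.

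The median number of genes detected at 1 TPM or more was 4306 per cell, with a range of 1487 to 5719. By group the median was 3489 in CMP, 4514 in Ly6C-GMP, 4829 in Ly6C+GMP, 4204 in proneu, 2373 in preNeu and 3082 in tpMo cells. The 20 most abundant genes of a cell took a median of 47.1% of TPM in preNeu cells, against 14.2 to 22.4% in the other groups. The mitochondrially encoded genes took 1.58% in preNeu cells and 3.58 to 5.73% elsewhere.

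The first comparison asked how CD16/32-high Ly6C-GMP cells differed from CD16/32-low CMP cells. Transcripts of the primary granules, the first granules made by neutrophil progenitors, had higher means in Ly6C-GMP cells. Elane, which encodes neutrophil elastase (chromosome 10, 79886247 to 79888215, plus strand of GRCm38), averaged 16018 ± 12133 TPM (SD over cells) in Ly6C-GMP cells and 1488 ± 4333 TPM in CMP cells, a ratio of 10.8. Ms4a3, a membrane protein gene of granulocyte-monocyte progenitors (chromosome 19, 11629496 to 11640851, minus strand), averaged 2190.1 ± 1604 against 156 ± 476 TPM, and the serine protease gene Ctsg averaged 5032 ± 2657 against 947 ± 1464 TPM. Of the 14 measured primary granule genes, 13 were higher by at least 1 log2 unit, 0 were lower and 1 lay within 1. The median difference of the list was 3.42, at percentile 100 of 10000 random lists matched on mean expression. Within title runs B and H it was 3.77 and 3.09.

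Some regulators of the neutrophil lineage were also higher in Ly6C-GMP than in CMP cells. Cebpe, a transcription factor gene required for terminal granulocyte maturation, was detected in 25 of 45 Ly6C-GMP cells (55.6%, 95% interval 40 to 70.4%) and in 1 of 47 CMP cells (2.13%, 95% interval 0.0539 to 11.3%). Exact intervals such as these cover counting error only. Spi1, which encodes the myeloid transcription factor PU.1, averaged 325 ± 263 against 191 ± 216 TPM. In this list 5 of 11 genes were higher, 0 lower and 6 within 1, with a median difference of 0.91 (percentile 95.2; 1.25 in run B and 0.55 in run H). Several transcripts of erythroid and megakaryocytic cells were lower in Ly6C-GMP cells. Car2, encoding carbonic anhydrase 2 (chromosome 3, 14886273 to 14900770, plus strand), averaged 619 ± 825 TPM in CMP and 63.6 ± 188 TPM in Ly6C-GMP cells. Mfsd2b, a sphingosine-1-phosphate transporter gene of red cells and platelets, was detected in 15 of 47 CMP cells and 1 of 45 Ly6C-GMP cells. Of the 16 genes of this list 0 were higher and 8 lower, with a median difference of −1.0 (percentile 0; −1.22 in run B and −0.70 in run H). Of 24 stem and multipotent progenitor genes 0 were higher and 9 lower, with a median difference of −0.37 (percentile 0; −0.58 in run B and −0.18 in run H). Among them, the homeobox gene Meis1 averaged 203 ± 288 TPM in CMP and 32.8 ± 108 TPM in Ly6C-GMP cells, and Angpt1, which encodes angiopoietin 1, was detected in 28 of 47 CMP (59.6%, 95% interval 44.3 to 73.6%) and 11 of 45 Ly6C-GMP cells (24.4%, 95% interval 12.9 to 39.5%). The erythroid and megakaryocyte median was −0.38 with no filter on low values and −3.19 as a ratio of mean TPM, and with a pseudocount of 10 TPM that of the regulators was 0.46. Without the Ly6C-GMP cell highest in each gene, the means of that group were 38 TPM for Car2 and 18.2 TPM for Meis1.

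Fcgr3, which encodes the gate marker CD16, averaged 691 ± 641 TPM in Ly6C-GMP and 91.4 ± 251 TPM in CMP cells, a difference set by the sort. The histamine-producing enzyme gene Hdc had a higher mean in Ly6C-GMP cells (407 ± 435 against 62.5 ± 220.3 TPM, the latter 39.2 TPM without the highest cell). Of the 9 basophil and mast cell genes 3 were higher and 1 lower, with a median difference of 0.74 (percentile 74.8). The mitosis list had a median of 0.64 over all cells (6 of 23 genes higher, 0 lower, percentile 53.7), of 0.73 in run B and of 0.058 in run H. As a ratio of mean TPM the mitosis list had a median of −0.20. DNA replication genes had a median of 0.48 (7 of 23 higher, 0 lower, percentile 19.2), so neither list stood apart from genes matched on mean expression. The median difference over all 12582 measured genes was 0.19.

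The second comparison set the cells labelled Ly6C+GMP against those labelled Ly6C-GMP. Proneu cells given the same gate as Ly6C+GMP were left out. The differences are therefore those of the labels and not of the whole Ly6C-positive gate. Monocyte transcripts had higher means in Ly6C+GMP than in Ly6C-GMP cells. F13a1, the coagulation factor XIII A chain gene expressed by monocytes (chromosome 13, 36867178 to 37050244, minus strand), was detected in 94.3% of Ly6C+GMP cells at a mean of 480.3 ± 480.5 TPM, and in 15 of 45 Ly6C-GMP cells at a mean of 147 ± 318 TPM. Ly86, a partner of a Toll-like receptor homologue, averaged 301 ± 332 against 147 ± 312 TPM. Of 23 measured monocyte genes 16 were higher, 0 lower and 7 within 1, with a median difference of 1.41 (percentile 100). It was not shared by both runs of Ly6C+GMP cells: against all Ly6C-GMP cells the median was 1.53 for the 95 Ly6C+GMP cells of run A (16 genes higher, 0 lower) and 0.20 for the 10 of run C (5 higher, 3 lower). Irf8, a transcription factor gene of the monocyte and dendritic lineages, was detected in 85 of 95, 2 of 10 and 19 of 45 of these groups. Ly6c2, which encodes the Ly6C gated on, averaged 8521 ± 2515 against 2398 ± 2583 TPM. The median over all 12399 genes was 0.12. No title run, as split here, held both labels, so run and label cannot be told apart in any value of this comparison.

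Many granule transcripts were higher in Ly6C+GMP cells as well. Of 14 primary granule genes 7 were higher and 0 lower, with a median difference of 1.06 (percentile 99.97). Gstm1, a glutathione transferase gene of that list, averaged 2152 ± 1118 against 1234 ± 1196 TPM, and the granule protease gene Prss57 averaged 541 ± 432 against 331 ± 364 TPM. In the list of secondary and late granule genes, which are expressed later in neutrophil maturation, 12 of 20 were higher and 0 lower, with a median difference of 1.74 (percentile 100). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, averaged 112 ± 112 against 23.4 ± 66.3 TPM, and the haptoglobin gene Hp averaged 777 ± 438 against 268 ± 362 TPM. Several genes of the list were not particular to neutrophil cells. Cybb averaged 542 TPM in tpMo cells. Lyz2 and Chil3 were higher in tpMo than in Ly6C+GMP cells, by 6.21 and 5.24, and Hp differed by 0.12. Of 18 list genes measured there, 5 were higher and 2 lower in tpMo cells. Between Ly6C+GMP and Ly6C-GMP cells, Mmp8, Mmp9, Retnlg and Pglyrp1 differed by −0.63, −0.37, −0.65 and −0.38. The list median alone thus does not mark a neutrophil programme. S100a8, a calcium-binding protein gene, was detected in 91.4% of Ly6C+GMP and 16 of 45 Ly6C-GMP cells, while its mean was lower in Ly6C+GMP cells (944 ± 2488 against 1681 ± 6822 TPM). Without the 3 Ly6C-GMP cells that had at least 1000 TPM of Ngp, a secondary granule gene, the S100a8 mean of that group was 27.2 TPM, which turns the direction of the means. As a ratio of mean TPM the list median was −0.041, and that of the primary granule list 0.39; without those 3 cells the median difference was 2.34.

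Low levels of the secondary granule transcripts were widespread in run A. Ngp was at 1 TPM or more in 95 of 95 Ly6C+GMP cells of that run, with a median of 33.8 TPM and an interquartile range of 23.6 to 48.2 TPM. The preNeu mean of Ngp was 4174 times that median. The medians were 4.51 TPM for Ltf and 13.6 TPM for Camp in the same cells, and in Ly6C-GMP cells the Ngp median was 0.715 TPM in run B and 0 TPM in run H. Chil3, a chitinase-like protein gene, had a median of 9.40 TPM in run A and a mean of 231 ± 1243 TPM over all Ly6C+GMP cells. Without the Ly6C+GMP cell highest in Chil3, which was the one highest in Ngp, the mean was 111 TPM.

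Mitosis genes, and fewer of the DNA replication genes, were higher in Ly6C+GMP than in Ly6C-GMP cells: 19 of 23 mitosis genes were higher and 0 lower (median 1.33, percentile 100; 1.40 with the Ly6C+GMP cells of run A and 2.34 with those of run C), and 11 of 23 DNA replication genes were higher and 0 lower (median 0.89, percentile 99.5). The mitotic kinase gene Cdk1 averaged 546 ± 412 against 352 ± 404 TPM, and Rrm2, a subunit of ribonucleotide reductase, 532 ± 349.8 against 222 ± 233 TPM. Of 8 basophil and mast cell genes 0 were higher and 3 lower (median −0.70, percentile 0.01). The mast cell carboxypeptidase gene Cpa3 averaged 686 ± 1402 TPM in Ly6C-GMP and 7.53 ± 55 TPM in Ly6C+GMP cells, and Gata2, a transcription factor gene of mast cells and stem cells, 49.2 ± 122 and 1.16 ± 10.7 TPM. With no filter on low values the basophil and mast cell median was −0.012. Among 21 stem and multipotent progenitor genes 1 was higher and 7 were lower (median −0.59, percentile 0), including Cd34, a gate marker, at 446 ± 339 and 178 ± 190.4 TPM. Without the Ly6C+GMP cell highest in each gene, Cpa3 averaged 2.27 and Gata2 0.112 TPM in that group.

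**Figure D1:**
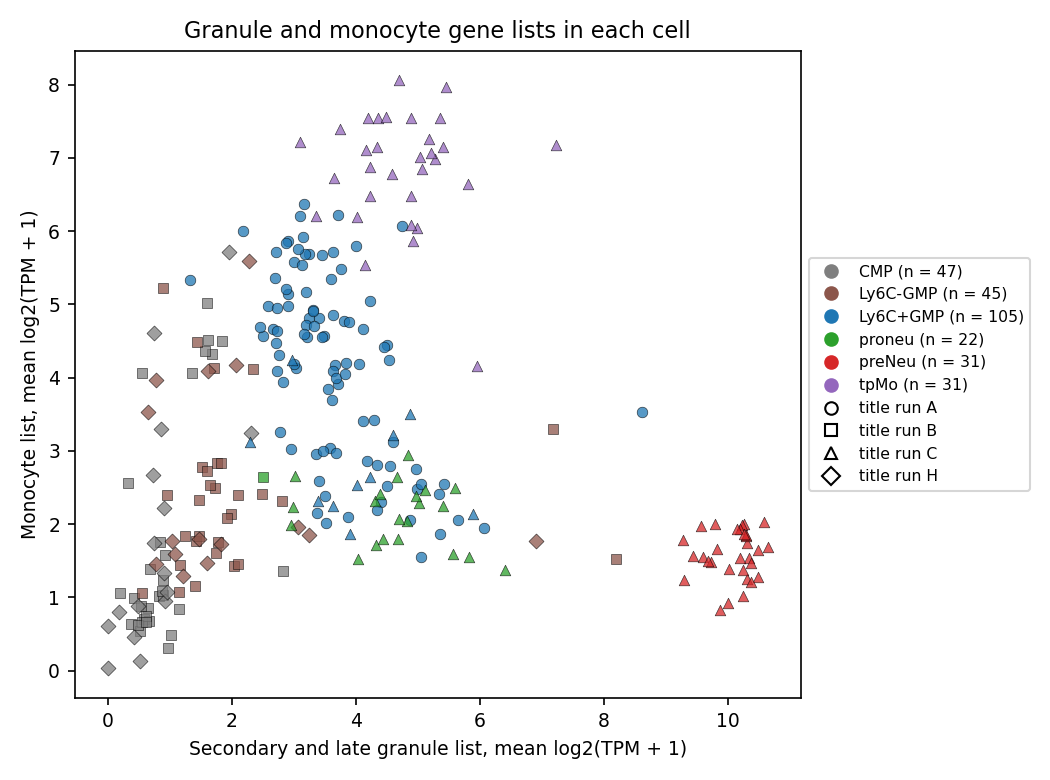
Each point is 1 of the 281 cells, with the mean log2(TPM + 1) of the secondary and late granule list on the x axis and of the monocyte list on the y axis; colours give the label and marker shapes the title run. The mean monocyte score was 4.04 in Ly6C+GMP, 2.15 in proneu, 1.58 in preNeu and 6.85 in tpMo cells, and the mean granule score was 3.71, 4.57, 10.1 and 4.74.

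The third comparison addressed the neutrophil progenitor named in the series title by setting proneu against Ly6C+GMP cells. Monocyte transcripts had lower means in proneu cells. Irf8 (chromosome 8, 120736358 to 120756694, plus strand) averaged 1.08 ± 1.98 TPM in proneu and 368 ± 361 TPM in Ly6C+GMP cells. Csf1r, which encodes the monocyte growth factor receptor CD115, was detected in 1 of 22 proneu and 56.2% of Ly6C+GMP cells. Ly86 averaged 27.3 ± 91.2 against 301 ± 332 TPM, and 9.78 TPM in proneu cells without the highest one. Of 23 monocyte genes 0 were higher, 15 lower and 8 within 1, with a median difference of −2.29 (percentile 0). Within run C, which held 21 proneu and 10 Ly6C+GMP cells, the median was −0.60, with 7 genes lower and 0 higher, and the differences were −0.90 for Irf8, −1.01 for Csf1r and −1.75 for Ly86. The Ly6C+GMP cells of run C had an Irf8 mean of 44.1 ± 117 TPM, against 402 ± 362 TPM in those of run A. In run C Irf8 was detected in 2 of 10 Ly6C+GMP cells, the higher at 373 TPM, so the run C mean rests mainly on 1 cell.

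Some secondary and late granule genes were higher in proneu cells and others were not. Fcnb, which encodes ficolin B (chromosome 2, 28076378 to 28084885, minus strand), averaged 1211 ± 1358 against 433 ± 1183 TPM, a difference of 3.54 over all cells and 1.97 in run C. Among the Ly6C+GMP cells of run C the highest had 8404 TPM of Fcnb and the next 441 TPM. S100a8 averaged 3615 ± 3905 against 944 ± 2488 TPM (4.43 over all cells, 2.21 in run C), and S100a9 509.9 ± 997 against 155 ± 834 TPM (3.12 and 2.69). Without the highest cell of each label the S100a9 means were 325 and 80.8 TPM. Of 18 genes 7 were higher, 2 lower and 9 within 1, with a median of 0.42 (percentile 100), of 0.55 in run C and of 0.055 with no filter on low values. The 2 lower genes were Lyz2 (−1.07) and Cybb (−1.14), which differed by 0.67 and 0.27 in run C, where 6 genes of the list were higher and 0 lower. The primary granule list had a median of 0.65 (percentile 100), with 4 of 14 genes higher and 2 lower, but of −0.028 in run C. Nkg7 and Prss57, both of that list, differed by 1.47 and 1.32 over all cells and by −0.0031 and −0.054 in run C. Gfi1, a transcriptional repressor gene of the neutrophil lineage, averaged 66.8 ± 81.1 against 17 ± 42.2 TPM (2.19 over all cells, 0.094 in run C). Of 12 neutrophil regulators 3 were higher and 3 lower, with a median of −0.054 (percentile 92.6), and in run C 0 were higher and 1 lower, with a median of −0.38 (percentile 47.2). Median Ngp was 93.8 TPM in the proneu and 23.7 TPM in the Ly6C+GMP cells of run C, against 89.6 TPM in the tpMo cells of that run. Between tpMo and Ly6C+GMP cells the secondary and late granule list had a median of 0.67 (5 higher and 2 lower of 18, percentile 100). In run C that median was 0.18, with 8 higher and 5 lower. A percentile of 100 for this list over all cells was thus not particular to proneu cells.

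Mitosis genes had lower means in proneu cells both over all cells and within run C. Of 23 genes 0 were higher and 14 lower, with a median of −1.25 (percentile 0.11); in run C 18 were lower and the median was −1.64. The cyclin gene Ccnb1 averaged 195 ± 360.2 against 325 ± 363 TPM, Ccna2 100.02 ± 144 against 175 ± 144 TPM, and the mitotic kinase gene Aurkb 193 ± 225 against 293 ± 253 TPM. Without the highest proneu cell the Ccnb1 mean was 128 TPM. As a ratio of mean TPM the list median was −0.44. Of 23 DNA replication genes 0 were higher and 7 lower (median −0.50, percentile 39.1). Over all 12026 genes the median difference was −0.23.

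**Figure D2:**
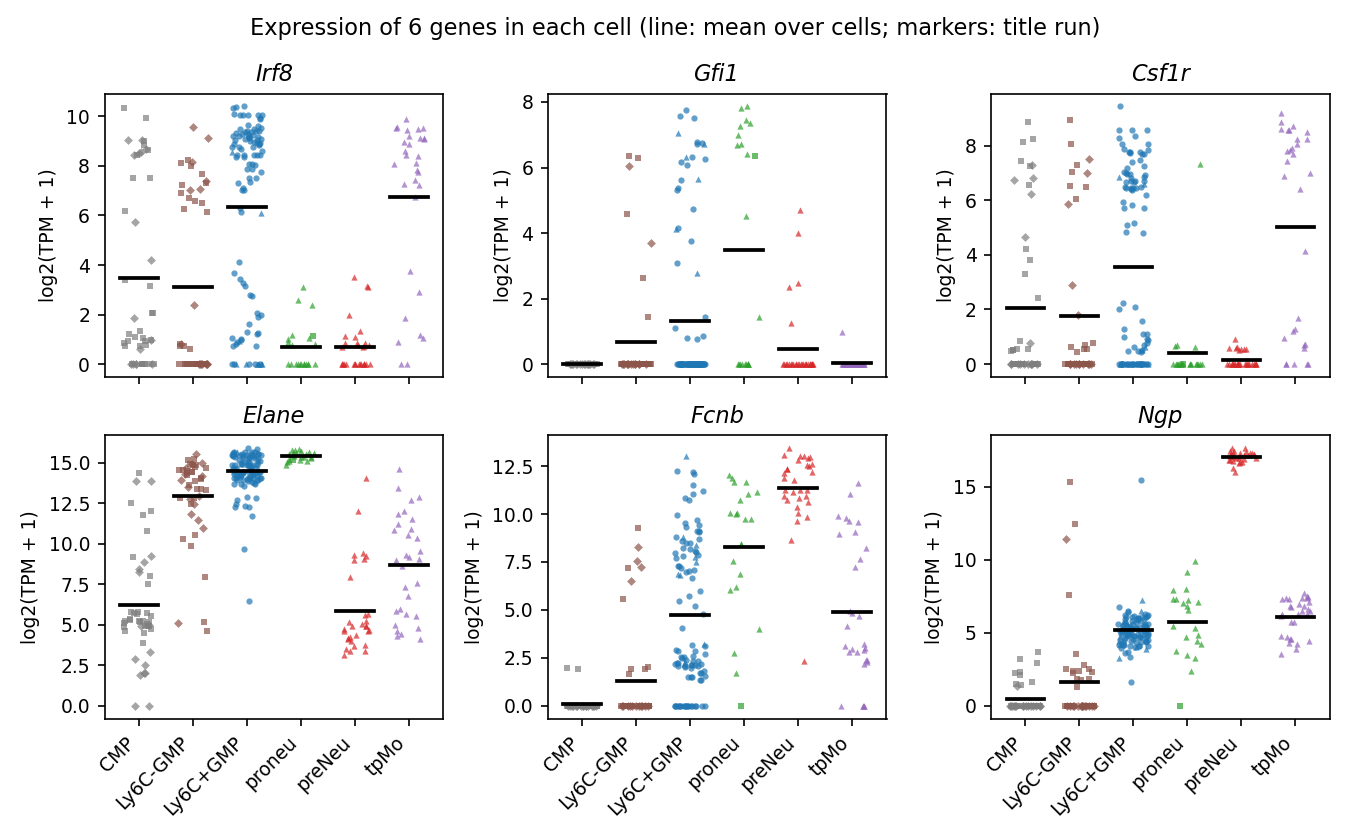
log2(TPM + 1) of Irf8, Gfi1, Csf1r, Elane, Fcnb and Ngp (y axis) in each cell of the 6 labels (x axis), with 1 point per cell, a marker shape for each title run and a line at the mean. Irf8 was at 1 TPM or more in 82.9% of Ly6C+GMP and 28 of 31 tpMo cells, and in 7 of 22 proneu and 7 of 31 preNeu cells.

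Gfi1 and Irf8, transcription factors of the opposing neutrophil and monocyte branches, were scored together in single cells. Gfi1 was detected in 12 of 22 proneu cells (54.5%, 95% interval 32.2 to 75.6%) and in 23.8% of Ly6C+GMP cells (16 to 33.1%). It was also found in 7 of 45 Ly6C-GMP and 5 of 31 preNeu cells. It was detected in 0 of 47 CMP cells, which allows a share of up to 7.55%, and in 0 of 31 tpMo cells, which allows up to 11.2%. Irf8 was detected in 82.9% of Ly6C+GMP cells (74.3 to 89.5%), 28 of 31 tpMo, 26 of 47 CMP and 19 of 45 Ly6C-GMP cells, and in 7 of 22 proneu cells (31.8%, 13.9 to 54.9%). The proneu share lay near that of preNeu cells (7 of 31, 22.6%), and at a limit of 10 TPM Irf8 was counted in 69.5% of Ly6C+GMP and 0 of 22 proneu cells. Both genes were detected in 13.3% of Ly6C+GMP cells (7.49 to 21.4%), 4 of 22 proneu cells (18.2%, 5.19 to 40.3%), 2 of 45 Ly6C-GMP, 1 of 31 preNeu and 0 of 47 CMP cells. At 10 TPM both were counted in 4.76% of Ly6C+GMP cells (1.56 to 10.8%) and 0 of 22 proneu cells, which allows up to 15.4%. In run C alone, Ly6C+GMP cells had Gfi1 in 6 of 10 and Irf8 in 2 of 10, and proneu cells had Gfi1 in 11 of 21 and Irf8 in 6 of 21. In run A, Ly6C+GMP cells had Gfi1 in 19 of 95 and Irf8 in 85 of 95.

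Clustering of the 172 Ly6C-GMP, Ly6C+GMP and proneu cells gave 6 clusters, compared here by number. Cluster 1 held 33 of 45 Ly6C-GMP cells (73.3%, 95% interval 58.1 to 85.4%), 2 Ly6C+GMP and 4 of 22 proneu cells. Ly6C+GMP cells spread over the other clusters, with 35 in cluster 2, 20 in cluster 3, 13 in cluster 4, 19 in cluster 5 and 16 in cluster 6. Proneu cells fell in cluster 3 (10 of 22, 45.5%, 24.4 to 67.8%), cluster 4 (8 of 22) and cluster 1. This spread depended on the settings, as 1 cluster held 100% of them at resolution 0.5 and 81.8% (59.7 to 94.8%) with the DNA replication and mitosis genes left out. Clusters 2, 5 and 6, which held no proneu cell (a count of 0 of 22 allows up to 15.4%), took 66.7% of Ly6C+GMP cells (56.8 to 75.6%). Of the 10 Ly6C+GMP cells of run C, 6 fell in cluster 3 and 0 in cluster 2. The genes that differ between the labels also shaped the clusters, so these shares restate the expression differences, and cluster 1 held 22 Ly6C-GMP cells and 1 proneu cell of run B, 11 Ly6C-GMP cells of run H, 2 Ly6C+GMP cells of run A and 3 proneu cells of run C.

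Proneu cells were set against preNeu cells of the Gr1-positive and CD11b-positive gate; all but 1 proneu cell were in run C. Primary granule transcripts had much lower means in preNeu cells. Mpo, which encodes myeloperoxidase (chromosome 11, 87793581 to 87804413, plus strand), averaged 47923 ± 11301 TPM in proneu and 152 ± 514 TPM in preNeu cells, a 315-fold ratio. Ctsg averaged 7675 ± 2323 and 3.85 ± 3.78 TPM, and Elane 43959 ± 8062 and 809 ± 3141 TPM. Without the preNeu cell highest in each gene, Mpo averaged 62.8 and Elane 262 TPM in that group. Of 14 primary granule genes 12 were lower, 0 higher and 2 within 1, with a median difference of −8.10 (percentile 0; −8.16 in run C). Secondary granule transcripts went the other way. Ltf, which encodes lactoferrin (chromosome 9, 111019271 to 111042767, plus strand), averaged 7.85 ± 8.27 TPM in proneu and 17946 ± 9279.6 TPM in preNeu cells, and the cathelicidin gene Camp 196 ± 530.0 (110.0 without the highest cell) and 46641 ± 14172 TPM. Ngp alone averaged 141178 ± 31973 TPM in preNeu cells, against 143 ± 219.9 TPM in proneu cells. Of 20 genes 15 were higher and 0 lower, with a median of 5.50 (percentile 100; 5.31 in run C). In tpMo cells, outside the neutrophil gates, the means were 11.1 ± 7.96 TPM for Ltf, 30.7 ± 28.3 TPM for Camp and 91.4 ± 60.8 TPM for Ngp. Lyz2, the lysozyme gene, averaged 509 ± 507 and 46321 ± 18862 TPM.

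Genes of ribosome biogenesis were lower in preNeu than in proneu cells throughout the list, with 19 of 19 lower and 0 higher (median −4.11, percentile 0; −3.99 in run C). Nop56, a nucleolar protein of box C/D small nucleolar ribonucleoproteins, averaged 531 ± 388 TPM in proneu and 18.1 ± 58 TPM in preNeu cells, and the nucleophosmin gene Npm1 1561 ± 558 and 115 ± 181 TPM. The mitochondrially encoded genes were lower as well, with a median of −3.26 (percentile 6.05), and preNeu cells had the fewest detected genes. DNA replication genes were lower in 19 of 23 cases and higher in 0 (median −2.90, percentile 3.09). The replicative helicase subunit genes Mcm6 and Mcm2 averaged 499 ± 203 and 197 ± 173 TPM in proneu cells, and 137 ± 289 and 39.7 ± 111 TPM in preNeu cells. Of 23 mitosis genes 11 were higher by at least 1, 1 lower and 11 within 1 (median 0.97, percentile 100; 0.82 in run C). The mitotic ubiquitin-conjugating enzyme gene Ube2c averaged 112 ± 212 TPM in proneu and 543 ± 570.4 TPM in preNeu cells, and the centromeric histone gene Cenpa 157 ± 268 and 556 ± 488 TPM. Of 12 stem and multipotent progenitor genes 1 was higher and 5 were lower (median −0.30, percentile 91.4). The transcription factor gene Myb averaged 161 ± 138 and 37 ± 65.4 TPM, and Kit, whose protein was part of both gates, 72.3 ± 81.9 and 8.51 ± 24.6 TPM. The median over all 10991 genes was −0.68, beside which these medians are to be read. DNA replication had a median of −0.96 as a ratio of mean TPM. Without the preNeu cell highest in each gene, the means of that group were 9.59 TPM for Nop56, 25.5 TPM for Mcm2 and 4.97 TPM for Kit.

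On the monocyte side, tpMo cells were set against Ly6C+GMP cells. Transcripts of mature monocyte functions had higher means in tpMo cells. Lgals3, which encodes galectin 3 (chromosome 14, 47367751 to 47386160, plus strand), averaged 3096 ± 1772 TPM in tpMo and 36.3 ± 116 TPM in Ly6C+GMP cells. The lysozyme gene Lyz2 averaged 55045 ± 26538 and 1347 ± 2307 TPM, the lysosomal protease gene Ctss 1186 ± 1014 and 79.8 ± 161 TPM, and the fibronectin gene Fn1 594 ± 524 and 1.88 ± 13.5 TPM. Of 24 monocyte genes 14 were higher and 2 lower, with a median of 2.38 (percentile 100). Within run C, with 10 Ly6C+GMP cells, 18 were higher and the median was 4.45. Primary granule genes were lower in tpMo cells in 13 of 14 cases and higher in 1 (median −6.30, percentile 0; −6.86 in run C). Mpo averaged 2033 ± 5625 TPM in tpMo and 34287 ± 10619 TPM in Ly6C+GMP cells, and Ms4a3 218 ± 698 and 3013 ± 1697 TPM. Without the highest cell, the Ly6C+GMP mean of Fn1 was 0.654 TPM, and the tpMo means of Mpo and Ms4a3 were 1256 and 115 TPM.

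Ribosome biogenesis genes were lower in tpMo than in Ly6C+GMP cells, 19 of 19 by at least 1 and 0 higher (median −3.30, percentile 0; −3.47 in run C). The small nucleolar ribonucleoprotein gene Nop58 averaged 80.6 ± 208 against 377 ± 251 TPM, and the growth regulator gene Myc 49.5 ± 134 against 315 ± 292 TPM. Kit, whose protein was excluded by the tpMo gate, was at 1 TPM or more in 0 of 31 tpMo cells, which allows a share of up to 11.2%, and in 82.9% of Ly6C+GMP cells. Mitosis genes had a median of −0.29 over all cells (2 higher and 5 lower of 23, percentile 99). Within run C their median was −1.24, with 2 higher and 13 lower. The proliferation marker gene Mki67 averaged 115 ± 98.7 against 40.1 ± 41.4 TPM, and Ccnb1 had a lower mean log2 value (−2.13) with a higher mean of 411 ± 886 against 325 ± 363 TPM. Without the highest tpMo cell the Ccnb1 mean was 269.8 TPM, which turns the direction of the means, and that of Nop58 was 48.6 TPM. For DNA replication 0 of 23 genes were higher and 11 lower (median −0.95, percentile 69), and as a ratio of mean TPM the median was 0.49. Ifitm3, an interferon-induced membrane protein gene, averaged 748 ± 542 against 57.3 ± 78.2 TPM. Of 13 interferon response genes 3 were higher and 2 lower (median 0.19, percentile 99.9). Over all 12057 genes the median was −0.50.

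**Figure D3:**
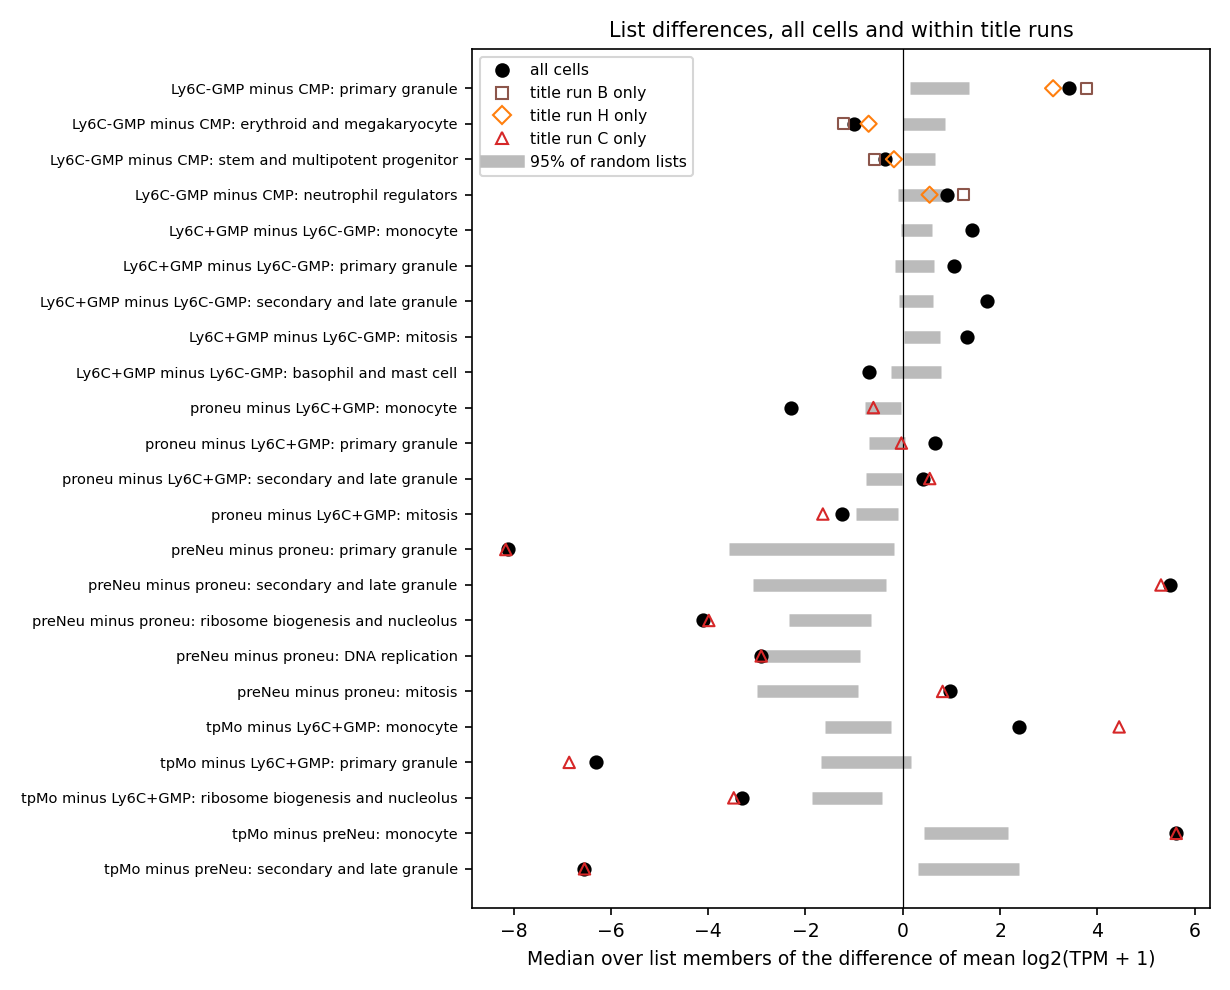
Median difference of mean log2(TPM + 1) over the members of the 23 leading gene lists of the 6 comparisons (y axis: lists; x axis: log2 difference), with markers for all cells and for single title runs and grey bars for the range of 95% of the random lists. The monocyte list had a median of −2.29 between proneu and Ly6C+GMP cells over all cells and of −0.60 within run C.

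The CD115-positive tpMo and Gr1-positive preNeu cells, all of run C, were then compared directly, with monocyte transcripts mostly higher in tpMo and secondary granule transcripts mostly higher in preNeu cells. F13a1 averaged 1915 ± 829.9 TPM in tpMo and 0.854 ± 0.818 TPM in preNeu cells. The monocyte surface protein gene Ms4a6c averaged 928 ± 575 and 1.36 ± 2.10 TPM, and the annexin partner gene S100a10 762 ± 416 and 0.140 ± 0.779 TPM. Of 24 monocyte genes 22 were higher in tpMo cells and 1 lower, with a median of 5.62 (percentile 100). Ctss, of the same list, averaged 1186 ± 1014 TPM in tpMo and 0.416 ± 0.844 TPM in preNeu cells. Of 20 secondary and late granule genes 16 were lower and 1 higher (median −6.54, percentile 0). Camp averaged 46641 ± 14172 TPM in preNeu and 30.7 ± 28.3 TPM in tpMo cells, and Ngp 141178 ± 31973 and 91.4 ± 60.8 TPM. Ngp was at 1 TPM or more in 31 of 31 tpMo cells, 21 of 21 proneu and 10 of 10 Ly6C+GMP cells of run C. Primary granule genes went the other way, with 8 of 14 higher in tpMo cells and 3 lower (median 1.83, percentile 81.5). Cebpe averaged 388 ± 501 TPM in preNeu and 29.7 ± 81.7 TPM in tpMo cells, and Itgam, which encodes the preNeu gate marker CD11b, 174 ± 185 and 16.9 ± 68 TPM. The preNeu mean of S100a10 came from 1 cell, and without its highest cell the tpMo mean of Itgam was 5.44 TPM.

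DNA replication and ribosome biogenesis genes were higher in tpMo than in preNeu cells. Mcm6 averaged 511 ± 424 TPM in tpMo and 137 ± 289 TPM in preNeu cells, and Npm1 846 ± 551 and 115 ± 181 TPM. Of 23 DNA replication genes 19 were higher and 0 lower (median 2.60, percentile 99.8), and of 17 ribosome biogenesis genes 13 were higher and 0 lower (median 1.53, percentile 99.9). Of 23 mitosis genes 3 were higher and 3 lower, with a median of −0.13 (percentile 0.01). The all-gene median was 0.36 over 10826 genes.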

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

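The alternatives that left out Ly6C-GMP or Ly6C+GMP cells with at least 1000 TPM of Ngp, or the proneu cell of run B, or that used only the Ly6C+GMP cells of 1 run, or left out the highest cell of a gene, were chosen after the data were seen. A change of sign was counted apart only where the main value was at least 0.5 in size for a list or 1 for a gene. Smaller values that changed sign were counted by the size of their shift. Of 198 values of the 23 list differences that lead the comparisons, 140 shifted by less than 0.58 on the log2 scale, which is 1.5-fold. A further 56 shifted by more, and 2 changed sign. For the other lists the numbers were 563, 80 and 3 of 646, and for named genes 598, 347 and 6 of 951. Leaving out cells with fewer than 1000 detected genes gave no values, as it removed 0 cells. No paired analysis was possible because replicate numbers only follow the accession order and pair no cells, and no test was made; differences within title runs were computed instead.

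A pseudocount of 10 TPM shrank log differences by construction, to 2.62 for primary granule (Ly6C-GMP with CMP), 0.55 for secondary granule and 0.66 for monocyte (Ly6C+GMP with Ly6C-GMP), −1.25 for monocyte (proneu with Ly6C+GMP), −6.23 for primary granule, 4.23 for secondary granule, −1.58 for DNA replication and −2.36 for ribosome biogenesis (preNeu with proneu), −5.02 for primary granule, 1.34 for monocyte and −1.74 for ribosome biogenesis (tpMo with Ly6C+GMP) and −4.96 for secondary granule and 3.77 for monocyte (tpMo with preNeu). One of 0.1 TPM widened them, to 3.22 for secondary granule, 2.38 for monocyte and 2.13 for mitosis (Ly6C+GMP with Ly6C-GMP), −2.95 for monocyte (proneu with Ly6C+GMP), −9.36 for primary granule, 6.51 for secondary granule, −3.83 for DNA replication and −6.43 for ribosome biogenesis (preNeu with proneu), −7.13 for primary granule, 3.13 for monocyte and −4.86 for ribosome biogenesis (tpMo with Ly6C+GMP) and −8.05 for secondary granule and 7.54 for monocyte (tpMo with preNeu). The log2 ratio of mean TPM, which weights cells with high values, gave 1.74 for primary granule, −3.19 for erythroid and −1.49 for stem (Ly6C-GMP with CMP), 0.39 for primary granule, −3.11 for basophil and 0.62 for mitosis (Ly6C+GMP with Ly6C-GMP), −0.44 for mitosis (proneu with Ly6C+GMP), −4.53 for primary granule, 4.39 for secondary granule and −0.96 for DNA replication (preNeu with proneu), −3.36 for primary granule and −1.74 for ribosome biogenesis (tpMo with Ly6C+GMP) and −4.52 for secondary granule and 7.24 for monocyte (tpMo with preNeu). Under it 6 values large enough to be counted apart changed sign. They were −0.041 for secondary granule genes and −0.83 for S100a8 (Ly6C+GMP with Ly6C-GMP). For Ly6C-GMP with CMP they were −0.20 for mitosis and −0.16 for ribosome biogenesis. For tpMo with Ly6C+GMP they were 0.49 for DNA replication and 0.34 for Ccnb1. The cause was not tested.

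Median-ratio scaling moved the median of all genes by 0.29 (preNeu with proneu), 0.11 (tpMo with Ly6C+GMP) and −0.16 (tpMo with preNeu). It gave −6.92 for primary granule, 7.21 for secondary granule, −1.82 for DNA replication, 2.04 for mitosis and −3.51 for ribosome biogenesis (preNeu with proneu). For tpMo with preNeu it gave −7.92 for secondary granule and 4.82 for monocyte. No list with a main difference of at least 0.5 in size changed sign. Without a filter on low values, the lists took in genes near 0 and gave 0.055 for secondary granule genes (proneu with Ly6C+GMP), −0.38 for erythroid (Ly6C-GMP with CMP) and −0.012 for basophil genes (Ly6C+GMP with Ly6C-GMP). Renormalising without the most abundant genes, several of them list members, gave 1.09 (Ly6C+GMP with Ly6C-GMP) and 4.62 (preNeu with proneu) for secondary granule genes. Leaving out the 3 Ly6C-GMP cells high in Ngp gave 2.34 for that list (Ly6C+GMP with Ly6C-GMP). Leaving out the Ly6C+GMP cell high in Ngp, or the proneu cell of run B, shifted none of the lists or genes by 0.58 or more. Against Ly6C-GMP cells, the Ly6C+GMP cells of run C alone gave 0.20 for monocyte and 2.34 for mitosis genes, and −1.25 for Ctsc, with changed sign; the cause was not tested.

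Within run C the values for proneu with Ly6C+GMP were −0.60 for monocyte genes and, with changed sign, −0.028 for primary granule genes, −0.054 for Prss57, −0.0031 for Nkg7 and 0.29 for Cd34. There the monocyte list of tpMo with Ly6C+GMP gave 4.45, and Ly6C+GMP cells had Irf8 in 20% and Gfi1 in 60%. The cause was not tested beyond the title run itself. Detection above 0 TPM gave Irf8 in 74.5% of CMP and 48.4% of preNeu cells. Detection at 10 TPM gave Irf8 in 36.2% of CMP, 69.5% of Ly6C+GMP, 3.23% of preNeu and 0% of proneu cells, and both genes in 4.76% of Ly6C+GMP, 0% of proneu and 0% of preNeu cells.

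Resolution 0.5 gave 2 clusters, and the cluster with most proneu cells then held 100% of them and 30.5% of Ly6C+GMP cells. Resolution 1.5 gave 9 clusters, with 62.2% of Ly6C-GMP cells in clusters without a proneu cell (22.2% at the main settings). That share was 66.7% with 1000 variable genes and 51.1% with 4000, where 11.4% of Ly6C+GMP cells were in the cluster with most proneu cells. Without cell cycle genes 81.8% of proneu cells shared a cluster. The cause was not tested. The number of genes detected per cell may limit shares near 0, above all in preNeu cells, with a median of 2373 genes. Read depth is unknown.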

Other observations

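The tests of the secondary granule list within run C, of the number of genes per cell on the mitosis list and of RNA from preNeu or tpMo cells in other libraries were chosen after the results were seen, while those of the title run on the monocyte list, of genes per cell on the primary granule list and of a few genes taking most of the TPM were set beforehand. Ighm, the immunoglobulin heavy constant mu gene of B cells, averaged 634 ± 441 TPM in Ly6C+GMP cells and was detected in 96.2% of them, against 155 ± 291 TPM and 25 of 45 Ly6C-GMP cells (chromosome 12, 113418558 to 113422730, minus strand). The Ly6C+GMP mean came from run A (683 ± 432 TPM), while the 10 cells of run C averaged 172 ± 192 TPM, near the Ly6C-GMP mean. In tpMo cells it averaged 1030.4 ± 859 TPM with 31 of 31 cells positive, and in preNeu cells 291 ± 391 TPM. The lymphoid list had a median difference of 0.16 (2 higher and 0 lower of 5, percentile 72.3) between Ly6C+GMP and Ly6C-GMP, and −0.30 (0 higher and 0 lower of 8, percentile 0.19) between Ly6C-GMP and CMP cells. Ifi27l2a, an interferon-induced gene, was listed at 0 in all preNeu cells and averaged 217 ± 378 TPM in tpMo cells, while the interferon response list had a median of 0.86 (6 higher and 1 lower of 12, percentile 87.5) between tpMo and preNeu cells.

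Dendritic cell genes had a median of −0.33 (2 higher and 1 lower of 7, percentile 0.72) between Ly6C-GMP and CMP and of −0.38 (0 higher and 0 lower of 6, percentile 0.61) between Ly6C+GMP and Ly6C-GMP cells. Eosinophil genes had 0.73 (1 higher and 0 lower of 4, percentile 85) and −0.47 (0 higher and 0 lower of 4, percentile 1.48) in the same comparisons, with Siglecf, an eosinophil lectin gene, at 24.7 ± 95.8 TPM (14.8 without the highest cell) in CMP and 65.3 ± 145 TPM in Ly6C-GMP cells. Immediate early and heat shock genes, which respond to handling, differed by 0.058 (1 higher and 0 lower of 12, percentile 18.8) between Ly6C-GMP and CMP and by 0.23 (2 higher and 2 lower of 13, percentile 99.9) between tpMo and Ly6C+GMP cells. The mitochondrially encoded genes had a median of −3.26 (0 higher and 10 lower of 12, percentile 6.05) between preNeu and proneu cells and of 2.08 (8 higher and 0 lower of 13, percentile 93.3) between tpMo and preNeu cells. Genes of the gates' surface proteins had −1.49 (5 higher and 11 lower of 19, percentile 51.9) between preNeu and proneu cells, where Ly6g, which encodes part of the Gr1 antigen, averaged 434 ± 797 against 2.32 ± 3.06 TPM.

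Single GMP cells were high in Ngp, with other late granule genes present or absent. Of the 45 Ly6C-GMP cells 3 had at least 1000 TPM of Ngp, and without them the group mean of Ngp was 5.88 TPM instead of 1090.4, and that of S100a8 27.2 instead of 1681 TPM. One, in run B, had 5582 TPM of Ngp with 28039 TPM of Mpo and 27209.6 TPM of Elane. Another in run B had 40544 TPM of Ngp with 3215 TPM of Mpo, 23.3 TPM of Elane and 0 TPM of Retnlg. Its other late granule genes were high, at 37213 TPM for S100a8, 20991 for Camp, 3357 for Chil3 and 2867 for Ltf. The one in run H had 2694 TPM of Ngp with 1324 TPM of Klf1 and 1501 TPM of Car1, genes of the erythroid lineage, and 10582 TPM of Retnlg, and 0 TPM of Camp, Ltf and Chil3. The single such Ly6C+GMP cell, in run A, had 46094 TPM of Ngp, 12676 TPM of Chil3, 8393 TPM of Mpo and 0 TPM of Retnlg. It also had 19117 TPM of S100a8, 8163 of Camp and 5503 of Ltf, with 87.1 TPM of Elane. Between preNeu and proneu cells Retnlg differed by 0.57, against 10.7 for Camp, so a Retnlg value of 0 does not set a cell apart from preNeu cells. Doublets were not called, and these genes were chosen after their values were seen.

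The monocyte list was lower in proneu than in Ly6C+GMP cells, with a median of −2.29, and the primary granule list had 0.65 (4 of 14 genes higher and 2 lower) and the secondary and late granule list 0.42. A difference between title runs may account for much of the first and the second of these, which were −0.60 and −0.028 in run C, but is argued against for the secondary list, at 0.55 there with 6 of 18 genes higher and 0 lower. The number of genes per cell, with a median of 4254 in proneu and 4918 in Ly6C+GMP cells of run C, is argued against as the whole source of the secondary list difference, which lay at percentile 100 among matched random lists within run C; it stays open for the monocyte and primary lists, at percentiles 12.7 and 94.9 there, since the bound set on the pooled 0.65 did not hold the run fixed. Traces of preNeu RNA stay open for part of the secondary difference, which without Ngp went from 0.53 to 0.28 in run C after subtracting the preNeu profile scaled to Ngp, and composition of the 10 Ly6C+GMP cells of run C could have lowered the monocyte difference there. Between tpMo and Ly6C+GMP cells, the same subtraction took the secondary list without Ngp from 0.66 to 0.056 over all cells. The biological explanation, a separate neutrophil progenitor under the proneu label, was not tested, as the label may rest on these transcriptomes.

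Ribosome biogenesis genes were lower in preNeu than in proneu cells, with a median of −4.11. After renormalising without the most abundant genes the median was −4.29. This cannot decide on a few genes taking most of the TPM. Rescaling leaves values of 0 at 0, so it restores no transcript missed because those genes took the reads. The mean score of the list was only 0.84 in preNeu cells, against 5.08 in proneu cells. The mitosis list was higher in preNeu cells at 0.97, so fewer genes per cell did not go with lower values in every list. That value was known before the test was chosen, and it bears only on the mitosis genes. The DNA replication and mitochondrially encoded lists were lower, at −2.90 and −3.26. A lower number of genes per cell therefore stays open as a source. Median-ratio scaling gave −3.51, with cell factors that ran from 0.0309 to 2.02 over all cells, so single cells were rescaled strongly. A lower share of ribosome biogenesis transcripts in preNeu cells thus stays a hypothesis, found on these same cells, and total RNA per cell is unknown.

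Traces of preNeu transcripts lay in all groups of runs A and C, with median Ngp of 33.8 TPM in run A Ly6C+GMP, 93.8 TPM in run C proneu and 89.6 TPM in tpMo cells, against 0 TPM in CMP cells of runs B and H. A candidate source is reads or RNA of preNeu cells: Ltf, Ngp, Camp and Chil1 in tpMo cells lay at 1 part in 1613, 1544, 1519 and 1090 of their preNeu means, and in the reverse direction Ctss, F13a1, Ifi30 and Pld4 lay lowest, down to a log2 ratio of −11.48 for Ctss. Over all 12 abundant preNeu genes the log2 ratios of means had an interquartile range of 6.84, wider than 1 common share would give. This range cannot decide on traces. The set holds genes high in tpMo cells themselves, such as Chil3 and Cybb, and a few high cells raise some means. The tpMo medians of S100a9, Lcn2 and Cd177 were 16.2, 8.22 and 2.09 TPM, against means of 115, 90.2 and 110 TPM. Without the highest tpMo cell the S100a9 mean was 63.5 TPM. Subtracting the preNeu profile scaled to Ngp took the secondary granule difference of Ly6C+GMP from Ly6C-GMP, without Ngp, from 1.63 to 1.16. This argues against preNeu traces in proportion to Ngp as the whole source. Traces of tpMo cells were not subtracted, so the subtraction does not cover them. Ltf went from 1.86 to 0.24 and Camp from 2.88 to 1.42, so for these 2 genes low own expression and traces are both open, and no biological explanation was tested.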
